A study of Mus musculus with 2 samples.

How the data were processed

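Gene expression was measured in mouse spleen on 2 one-colour Agilent arrays, 1 for a pool of spleens given phosphate-buffered saline (PBS) and 1 for a pool of spleens remodelled with silica (SiO2). Per the labels, each pool held 5 spleens of female mice, taken on day 19 after the first injection. The groups have no replicates, so no test, p-value or standard deviation between animals could be given, and differences are described by fixed rules of size. The series design names further comparisons with fibroblasts, hepatocyte-like cells, hepatocytes, hepatized spleens and liver, which were not analysed here.

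Per the labels' protocols, RNA was taken with a kit made for blood that lyses red and white cells separately, globin message was reduced, and cRNA was labelled with Cy3. The deposited scanner files hold the intensity of each spot on a linear scale; per the file headers they were made with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1. The processed intensity used here is background-subtracted by that software, per the file headers. The authors' deposited series matrix holds log2 values for 26049 probes, with medians of 5.68 in both columns. Set against the scanner values, these had a slope of 0.994 in the PBS column and 1.01 in the SiO2 column over probes above background, and a correlation of 0.991 and 0.992. Their scale is thus log2 and their sign is that of the signal, while the method that brought the medians together and set a lowest value is not given in the sources used here.

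Each array carried 43020 spots that were not controls. Outlier flags removed 145 spots on the PBS array and 148 on the SiO2 array, and no spot was saturated. Spots well above background made up 75.5% on the PBS array and 74.9% on the SiO2 array. The main value was log2 of the processed intensity minus its 75th percentile on that array, which was a signal of 670 for PBS and 469 for SiO2. Repeated spots of a probe were averaged. Probes were named by matching their accession, without version, to the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 39398 probes kept, 27217 (69.1%) matched 1 gene symbol and 12181 matched none. The named probes stood for 20649 symbols, of which 16774 had a probe well above background on at least 1 array.

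A gene was given by the brightest of its probes that were well above background on at least 1 array. Where that probe was not well above background on the other array, its value there was raised to the lowest value of any probe above background on that array if it lay under it. The probe's own signal would give a larger difference, so this one is called a bound and written as at least N-fold. Of 491 genes above background in PBS only, 386 were treated so, and of 380 in SiO2 only, 299. In the other 105 and 81 the probe's own signal lay above that lowest value although it was not above background, and was kept, so the difference is no bound. The lowest value is thus no upper limit of undetected signal. For 9 further genes, another probe was above background on the dim array. Among 4325 genes with several probes, 360 differed at least 2-fold, and in 328 of these all probes had the same sign. No gene had 1 probe at least 2-fold higher and another at least 2-fold lower.

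Genes were counted at a difference of at least 2-fold (log2 of 1) and at least 4-fold (log2 of 2). For 40 gene lists fixed before the data were examined, the median log2 difference was ranked among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart at or above percentile 97.5 or at or below percentile 2.5, as a description of these arrays and not a test. The genes named were also chosen by a rule set in advance. It took the 15 largest differences per direction among genes measured on both arrays and the 5 largest differences per direction among genes above background on 1 array only, leaving out clone names, unnamed transcripts and receptor segments. It took, from each list, up to 5 members per direction that differed at least 2-fold and the members nearest the median where that was within 2-fold, and the control genes Gapdh, Actb, Hprt and the Y-linked genes. Some genes that this rule takes are not reported here. Further lists and genes in the closing section were chosen after the data were seen, as stated there.

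The error these files can give is technical. The standard deviation of log2 signal among the 10 spots of repeated probes had a median of 0.059 on the PBS array (317 probes) and 0.065 on the SiO2 array (318 probes). For the difference between the arrays it had a median of 0.063 and a 95th percentile of 0.228 (312 probes). These values cover spots and not animals, pools, labelling or hybridisation. Of 10 E1A spike-in probes, 3 were above background on each array. Their median signals before scaling were 251, 22.4 and 14.4 in PBS and 122, 21.0 and 12.2 in SiO2. These did not shift evenly, so the error between the arrays can be larger than that among spots. Both arrays came from 1 scan, so scan was shared, while the position on the slide and the group cannot be told apart.

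The alternatives tried were normexp background correction with an offset of 50, scaling to the median, quantile normalization, cyclic loess, the authors' deposited values, a filter on both arrays, no filter and no floor, the mean over a gene's probes, saturated probes left out, and random lists without matching. Normexp had been planned on the mean spot signal, which these files do not hold, and was run on the median spot signal and the median background. Scaling to spike-in probes was planned and not run. A pair of centrings on B and T cell markers was added after seeing the data.

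The steps were tested on simulated data made from the real levels and the technical noise. For the SiO2 against PBS comparison over 16774 genes, 0 of 67 genes given a 1.5-fold difference, 67 of 67 given a 3-fold difference and 66 of 66 given a 6-fold difference passed the 2-fold rule, as did 0 of 16574 genes given none. All genes were given the median noise among repeated spots, 0.063 on the log2 scale, so these outcomes were nearly fixed in advance. They check the steps and give no rate of false calls between pools. Of 100 random lists of 20 genes, 7 stood apart unshifted and 95 did so after a shift of 0.5 on the log2 scale. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.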

Results

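The 2 arrays compared spleens remodelled with silica (SiO2) with spleens given PBS as control. Each array held the RNA of a pool of 5 spleens of female mice taken on day 19 after the first injection. The comparison asks how gene expression in the remodelled spleen differs from that of the control spleen. There were no replicates, so the values below describe these pools, and the number of arrays limits their precision. Differences are log2 signal of the SiO2 pool minus that of the PBS pool, each relative to the 75th percentile of its array. Spots well above background made up 75.5% on the PBS array and 74.9% on the SiO2 array.

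The largest differences in the SiO2 spleen included single phagocyte and matrix genes on the higher side and genes of the mesothelium that covers the organ on the lower side. Gpnmb, a glycoprotein of lipid-laden phagocytes, was 38.5-fold higher, and Spp1, the secreted matrix protein osteopontin, was 14.1-fold higher. Atp6v0d2, a subunit of the lysosomal proton pump, was above background in the SiO2 pool only and 49.5-fold higher after scaling. Its unscaled signals were 294 in SiO2 and 8.47 in PBS, the latter not above background. Msln, the mesothelial surface protein mesothelin, was 39.4-fold lower, and Upk3b, another mesothelial membrane protein, was 33.9-fold lower, with a signal of 8.38 near background in the SiO2 pool. Under normexp the log2 differences were 3.88 in place of 5.27 for Gpnmb, 1.89 in place of 3.82 for Spp1, 2.72 in place of 5.63 for Atp6v0d2, -3.95 in place of -5.30 for Msln and -2.37 in place of -5.09 for Upk3b. Of 16774 named genes, 1111 (6.62%) were at least 2-fold higher in the SiO2 pool and 620 (3.70%) at least 2-fold lower. At 4-fold the numbers were 159 higher and 81 lower. With normexp background correction of the median spot signal, 655 genes were at least 2-fold higher and 259 lower. With the SiO2 array shifted so that B and T cell markers had a median difference of 0, an alternative chosen after seeing the data, 2622 were higher and 248 lower.

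Other genes among the 15 largest differences on the higher side were Vsig8 (17.4-fold), the chemokine Ccl8 (13.2-fold), the neurokinin precursor Tac2 (12.5-fold), the peptide transporter Slc15a2 (11.1-fold) and the small proteoglycan Aspn (10.2-fold). The macrophage elastase Mmp12 was 9.20-fold higher, the neutrophil granule protein Ngp 8.77-fold, the Wnt antagonist Sfrp4 8.74-fold, Clgn 8.16-fold and Col8a1 8.09-fold. The iron-binding protein Ltf was 7.80-fold higher, the lipid-sensing receptor Trem2 7.79-fold and the antisense transcript Zfhx2os 7.35-fold. The bounds on the higher side were at least 22.2-fold for Ccn3, 11.2-fold for Cthrc1 and 8.52-fold for Calca. Lrrc17 was 8.70-fold higher, with a PBS signal that was not above background. On the log2 scale under normexp, Ccn3 was at 1.86, Cthrc1 at 1.45, Calca at 1.30 and Lrrc17 at 1.13. On the lower side, Retnla, a secreted protein of alternatively activated macrophages, was 18.0-fold lower and Lrrn4 16.9-fold lower. Prg4, which encodes lubricin, was 18.3-fold lower by its brightest probe, while its other probe gave a log2 difference of 0.74. Gbp2b, an interferon-induced GTPase, was 12.9-fold lower, Nkain4 12.8-fold, Gpm6a 9.51-fold, Efemp1 9.49-fold, the Wnt co-agonist Rspo1 9.20-fold and Igfbp6 8.62-fold. Anxa8 was 12.1-fold lower, and its other probe gave a log2 difference of -0.98. The chemokine receptor Xcr1 was 7.75-fold lower, Apol9b 7.38-fold and Pcnx2 7.20-fold. The bounds on the lower side were at least 14.4-fold for Upk1b, 14.1-fold for the keratin Krt19, 11.3-fold for Bnc1, 8.22-fold for Chst4 and 6.94-fold for Lrp2. Under normexp, Pcnx2 (-0.74), Bnc1 (-0.90), Chst4 (-0.48) and Lrp2 (-0.51) were within 2-fold on the log2 scale, and Upk1b was at -1.13 and Krt19 at -1.085. All of the 15 largest differences per direction were smaller under normexp. Among those dim on 1 array, Mmp12 was then at 1.60 and Zfhx2os at 1.11 on the log2 scale. Retnla was at -2.06, Lrrn4 at -1.64, Gbp2b at -1.65 and Anxa8 at -1.37.

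**Figure D1:**
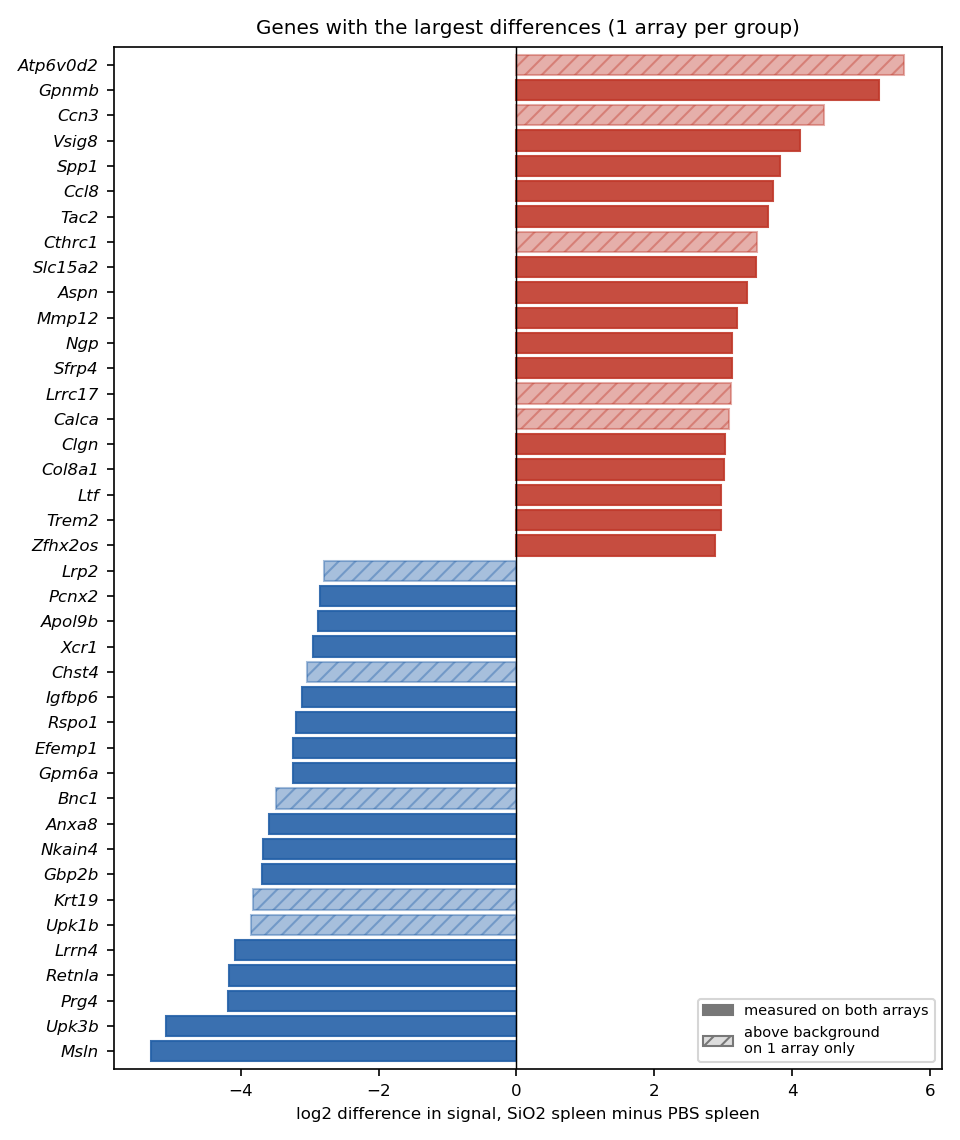
Bars show the log2 difference in signal, SiO2 spleen minus PBS spleen, for the 15 largest differences per direction measured on both arrays and, hatched, the 5 largest per direction among genes above background on 1 array only. Among genes measured on both arrays the extremes are Gpnmb at 5.27 and Msln at -5.30, with 1 array per group and no error bars.

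Of the 40 gene lists fixed in advance, 6 had a median among the highest 2.5% of random lists and 14 among the lowest 2.5%. If list members behaved like genes of matched signal drawn at random, 2 in all (5%) would be expected. Members of the same list can differ together, which the random lists do not model, so the excess over 2 is not a test. Setting the median difference of B and T cell markers to 0 adds 0.41 to the median of each list, so medians between -0.41 and 0 then lie above 0. The lists that stood apart on the higher side were those of erythroid, cell cycle, neutrophil, collagen, matrix glycoprotein and adipocyte genes.

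**Figure D2:**
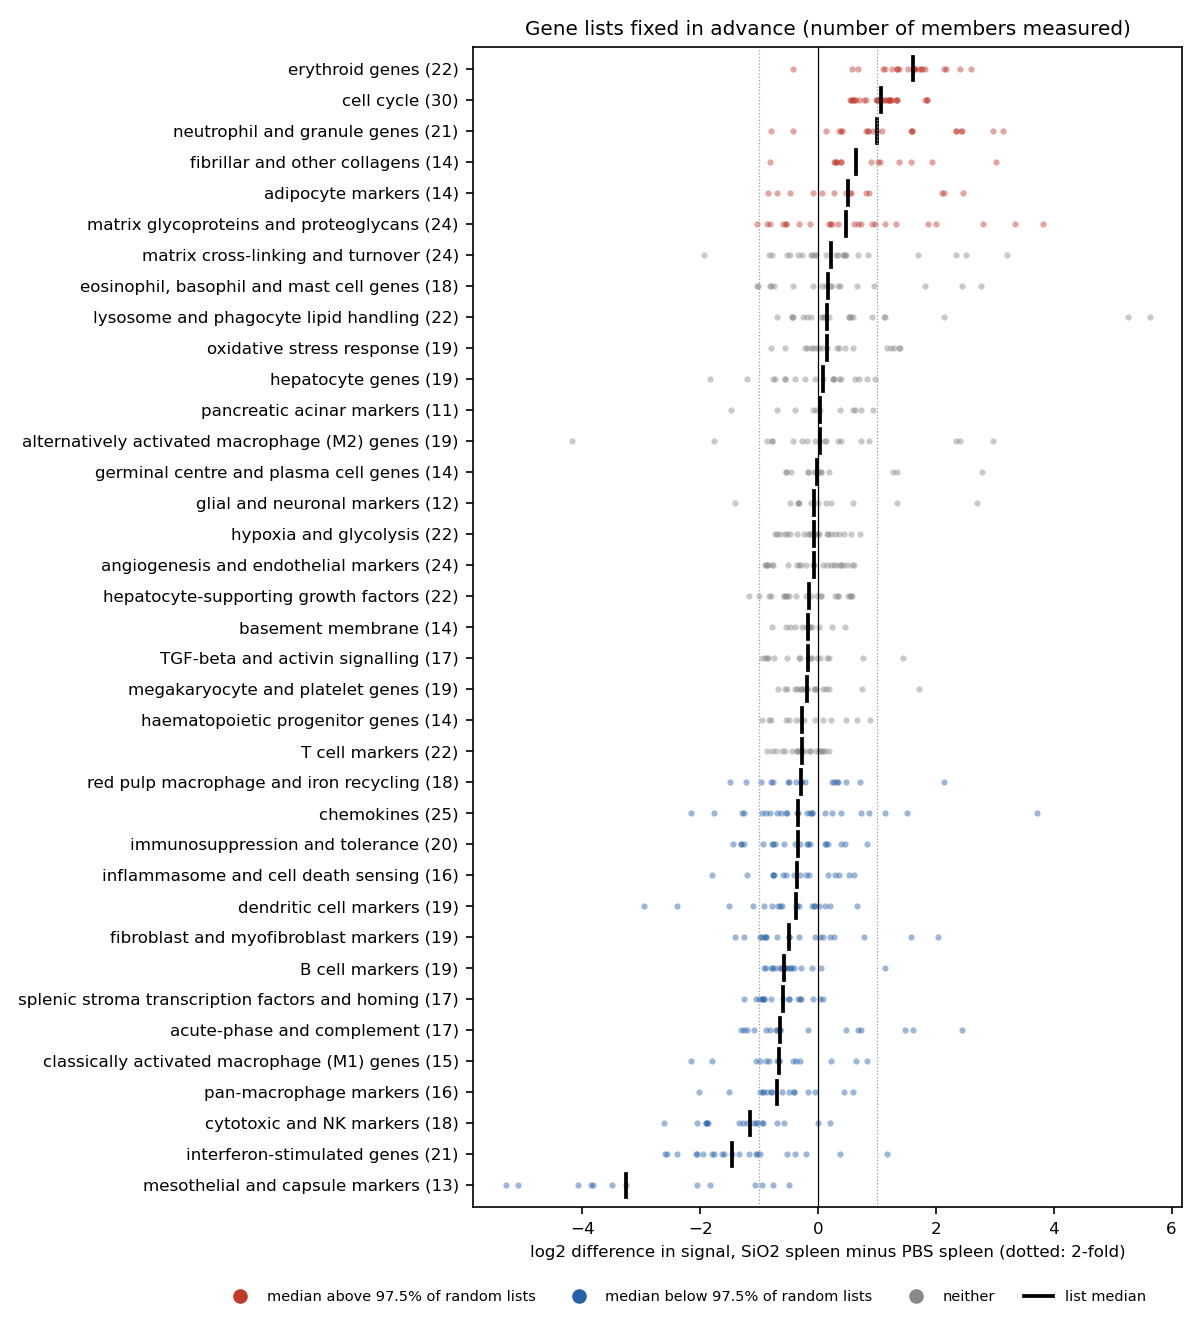
Each point is a gene and each black bar the median of its list, as the log2 difference in signal of the SiO2 spleen minus the PBS spleen, for the lists other than control lists. Medians run from 1.61 for erythroid genes to -3.25 for mesothelial markers, and red and blue mark lists that stood apart from random lists.

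A list of fibrillar and other collagens, the latter of types VI, VIII, XIV, XV and XVI, stood apart on the higher side. Of 14 measured, 6 were at least 2-fold higher and none lower, with a median log2 difference of 0.65 (percentile 100). Col8a1, which is not a fibrillar collagen, was 8.09-fold higher, and the fibrillar Col3a1 3.82-fold, Col1a1 3.00-fold and Col5a1 2.60-fold. Matrix glycoproteins and proteoglycans had 7 of 24 members at least 2-fold higher and 1 lower, with a median of 0.48. Beside Spp1 and Aspn, the keratan sulfate proteoglycan Lum was 6.96-fold higher and periostin, Postn, 4.02-fold. Ogn was 2.04-fold lower, or -0.72 on the log2 scale under normexp. Mfap2 was 3.65-fold higher by its brightest probe, and its other probe gave -0.52 on the log2 scale. In the authors' deposited values both medians were smaller, at 0.31 for the collagens and 0.26 for the glycoproteins, and still among the highest 2.5% of random lists. Genes of matrix cross-linking and turnover did not stand apart as a list (median 0.22, percentile 90.9), with 4 of 24 at least 2-fold higher and 1 lower. The collagen cross-linking enzyme Lox was 5.70-fold higher, the collagenase Mmp8 5.10-fold and the gelatinase Mmp2 3.25-fold, while the collagenase Mmp13 was 3.80-fold lower. Basement membrane genes had a median of -0.17 (percentile 15.2) and 0 of 14 members differing 2-fold.

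Fibroblast and myofibroblast markers had a median of -0.49 (percentile 0.02), with 2 of 19 at least 2-fold higher and 2 lower. Lrrc15, a marker of activated fibroblasts, was 4.09-fold higher, or 0.84 on the log2 scale under normexp, and Col1a1 was higher as above. The smooth muscle protein calponin, Cnn1, was 2.65-fold lower and the B cell attracting chemokine Cxcl13 2.39-fold lower. The median was -0.32 with the mean over a gene's probes. Of the 19 members, 7 were above 0 and 12 below. Beside Cnn1, those below included the contractile genes Myl9 (-0.98), Tpm2 (-0.96), Acta2 (-0.91), Tagln (-0.88) and Des (-0.49). Of 17 genes of TGF-beta and activin signalling, 1 was at least 2-fold higher, the activin subunit Inhba at 2.71-fold, or 0.70 on the log2 scale under normexp. The median of this list was -0.17 (percentile 16.2). With the mean over a gene's probes it was -0.27 (percentile 2.29) and stood apart. Transcription factors and homing genes of the splenic stroma had a median of -0.59 (percentile 0.01), with 2 of 17 at least 2-fold lower and Nkx2-3, a homeobox factor of spleen development, at -0.50.

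Macrophage genes differed in both directions. Pan-macrophage markers had a median of -0.69 (percentile 0), with 2 of 16 at least 2-fold lower, the Fc receptor Fcgr1 at 4.04-fold and Aif1 at 2.83-fold. Red pulp macrophage and iron recycling genes had a median of -0.29 (percentile 0.54), with 2 of 18 at least 2-fold lower and 1 higher. Spic, the transcription factor of red pulp macrophages, was 2.80-fold lower and Cd5l 2.33-fold lower, whereas the transferrin receptor Tfrc, also an erythroid gene, was 4.42-fold higher. Under normexp that list median was -0.20 and no longer stood apart, and with the median difference of B and T cell markers set to 0 it was 0.12. Genes of the lysosome and phagocyte lipid handling had 5 of 22 members at least 2-fold higher and none lower, with a median of 0.16 (percentile 89.1). Beside Gpnmb and Atp6v0d2, the fatty acid binding proteins Fabp4 and Fabp5 were 4.39-fold and 2.16-fold higher and the protease cathepsin K, Ctsk, 2.21-fold higher. Genes of alternative (M2) macrophage activation had a median of 0.03 (percentile 45.4), or -0.05 in the authors' deposited values, with 3 of 19 at least 2-fold higher and 2 lower. Trem2, Chil4 (5.33-fold) and Chil3 (5.06-fold), which is also in the neutrophil list, were higher. Retnla and Ccl24 (3.39-fold, or -0.54 on the log2 scale under normexp) were lower. Genes of classical (M1) activation had a median of -0.67 (percentile 0) and 3 of 15 at least 2-fold lower, namely Cxcl10 (4.47-fold), Il1b (3.48-fold) and Il12a (2.08-fold). Il12a was at -0.65 on the log2 scale under normexp.

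Inflammatory mediators also differed in both directions. Inflammasome genes had a median of -0.36 (percentile 0.97), or 0.050 with the median difference of B and T cell markers set to 0, with 2 of 16 at least 2-fold lower, Il1b and Il18 (2.32-fold). Chemokines had a median of -0.33 (percentile 0.2), with 3 of 25 at least 2-fold higher and 4 lower. Ccl8, the eosinophil attractant Ccl11 (2.84-fold) and Ccl9 (2.19-fold) were higher, and Cxcl10, Ccl24, Ccl12 (2.44-fold) and Cxcl13 lower. Of these, Ccl11 (0.88), Ccl9 (0.999), Ccl24 (-0.54) and Ccl12 (-0.21) were within 2-fold on the log2 scale under normexp. With no filter and no floor the chemokine median was -0.17 and did not stand apart, and with the median difference of B and T cell markers set to 0 it was 0.076. Acute-phase and complement genes had a median of -0.65 (percentile 0), with 3 of 17 at least 2-fold higher and 4 lower. The acute-phase proteins Lcn2 (5.46-fold), Orm1 (3.04-fold) and Saa3 (2.77-fold) were higher, and Fgl2 (2.47-fold) and the complement genes Cfb (2.37-fold), C1ra (2.31-fold) and C6 (2.12-fold) lower. Under normexp that median was -0.20, and Orm1 (0.73), Saa3 (0.77) and C6 (-0.20) were within 2-fold on the log2 scale. Genes of immunosuppression and tolerance had a median of -0.35 (percentile 0.52) and 4 of 20 at least 2-fold lower. These were Cd274 (the checkpoint ligand PD-L1) at 2.72-fold, Havcr2 at 2.46-fold, Lgals9 at 2.37-fold and Vsig4 at a bound of 2.47-fold. On the log2 scale under normexp, Lgals9 was at -0.74 and Vsig4 at 0.042. In the authors' deposited values the median of this list was -0.30 and did not stand apart, and with the median difference of B and T cell markers set to 0 it was 0.060.

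Interferon-stimulated genes were lower in the SiO2 pool. Of 21 measured, 15 were at least 2-fold lower and 1 higher, with a median of -1.46 (percentile 0). The nucleic acid sensor Zbp1 was 6.06-fold lower, Oas2 5.88-fold, Ifi44 5.27-fold, Ifit3 4.19-fold and Gbp2 4.13-fold, while the antiviral gene Rsad2 was 2.26-fold higher. Cytotoxic and natural killer (NK) cell markers had 12 of 18 members at least 2-fold lower and none higher, with a median of -1.15 (percentile 0). The granzymes Gzma and Gzmb were 6.15-fold and 4.17-fold lower, and the NK receptors Klre1, Klra8 and Klrb1c 3.73-fold, 3.71-fold and 3.69-fold lower. On the log2 scale under normexp, Klre1 (-0.62) and Klrb1c (-0.89) were within 2-fold, while Klra8 was at -1.77. Under the alternatives listed in advance the list median ranged from -1.22 to -0.79. Dendritic cell markers had a median of -0.37 (percentile 0.13), with 4 of 19 at least 2-fold lower. Among these were Xcr1 and Clec9a (5.25-fold), both marking cross-presenting dendritic cells, as well as Bst2 (2.84-fold) and Batf3 (2.14-fold). The dendritic cell median was -0.68 in the authors' deposited values and 0.034 with the median difference of B and T cell markers set to 0.

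B cell markers had a median of -0.57 (percentile 0), with Blk at -0.57 and 1 of 19 at least 2-fold higher, Cd24a at 2.19-fold. T cell markers had a median of -0.27 (percentile 3.37), with 0 of 22 differing 2-fold and Cd3d at -0.26. Germinal centre and plasma cell genes had a median of -0.02 (percentile 40.4), or 0.06 under normexp, with 3 of 14 at least 2-fold higher. Among these were Mki67 (2.53-fold) and S1pr2 (2.42-fold).

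Of the 40 lists, erythroid genes had the highest median in the SiO2 pool. Of 22 measured, 19 were at least 2-fold higher and none lower, with a median of 1.61 (percentile 100). The red cell membrane protein Epb42 was 6.08-fold higher, Kel 4.50-fold and Ank1 3.54-fold. Cell cycle genes were higher in 30 of 30 members, 20 of them at least 2-fold, with a median of 1.07 (percentile 100). Nusap1 was 3.61-fold higher, the spindle motor Kif11 3.60-fold, the cyclins Ccna2 and Ccnb2 3.53-fold and 2.54-fold, and the proliferation marker Mki67 2.53-fold. Neutrophil and granule genes had 11 of 21 at least 2-fold higher and none lower, with a median of 1.01 (percentile 100). Ngp, Ltf, Lcn2, the antimicrobial peptide Camp (5.39-fold) and Mmp8 led this list. Eosinophil, basophil and mast cell genes had a median of 0.17 (percentile 79.0), with 3 of 18 at least 2-fold higher and 2 lower. The eosinophil granule genes Epx and Prg2 were 6.77-fold and 5.43-fold higher and the basophil protease Mcpt8 3.54-fold. Ccr3 was 2.02-fold lower and Cma1 had a bound of 2.05-fold lower. On the log2 scale under normexp, Epx was at 1.15, Prg2 at 2.06, Mcpt8 at 1.25, Ccr3 at -0.81 and Cma1 at 0.22. Megakaryocyte and platelet genes had a median of -0.19 (percentile 7.82), or 0.07 under normexp, with 1 of 19 at least 2-fold higher, Nfe2 at 3.30-fold, a factor shared with erythroid cells. Progenitor genes had a median of -0.27 (percentile 4.32) and 0 of 14 differing 2-fold.

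**Figure D3:**
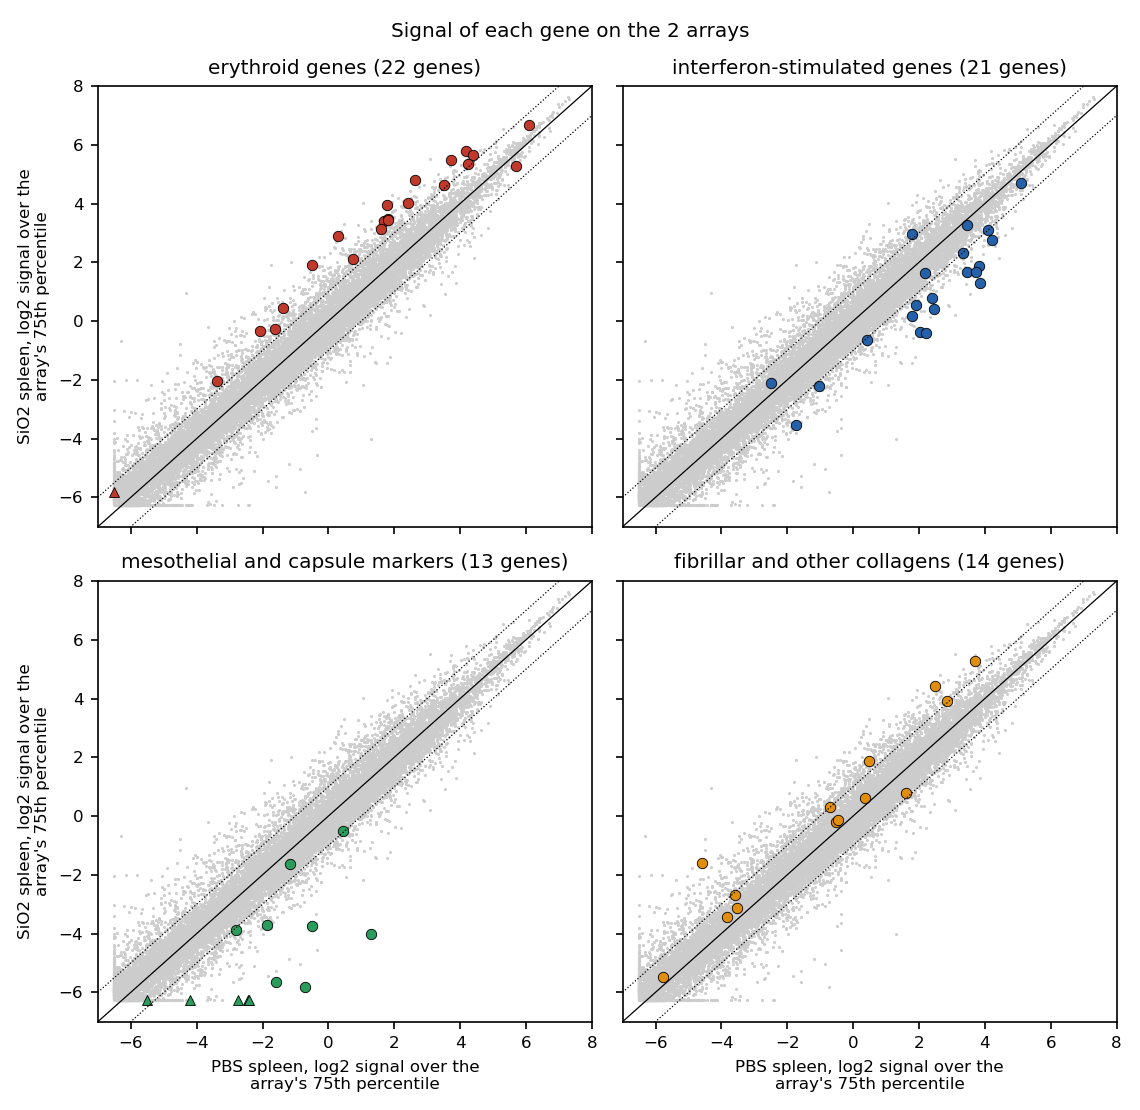
Each grey point is a gene, with log2 signal over the 75th percentile of the array in the PBS spleen (x axis) and the SiO2 spleen (y axis); coloured points are the members of 1 list, triangles are genes not above background on 1 array, the line marks equality and the dotted lines 2-fold. Of the coloured genes, 19 of 22 erythroid genes lie at least 2-fold above the line, and 15 of 21 interferon-stimulated and 10 of 13 mesothelial genes at least 2-fold under it.

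Mesothelial and capsule markers had the lowest median of the 40 lists. Of 13 measured, 10 were at least 2-fold lower and none higher, with a median of -3.25 (percentile 0). Of these members, 5 were above background on 1 array only. Under normexp the median was -0.90. Adipocyte markers had a median of 0.51 (percentile 99.4), with 3 of 14 at least 2-fold higher. These were the glucose transporter Slc2a4 (5.47-fold), Fabp4 (4.39-fold), also in the phagocyte lipid list, and the adipokine Adipoq (at least 4.32-fold). Adipoq was at 0.76 on the log2 scale under normexp. In the authors' deposited values the median of adipocyte markers was 0.22 and did not stand apart. Glial and neuronal markers had a median of -0.06 (percentile 22.7), or 0.30 under normexp, and a mean of 0.17, with 2 of 12 at least 2-fold higher and 1 lower. Gfap was 6.52-fold higher by its brightest probe and its probes ranged from 0.63 to 2.70 on the log2 scale. Snap25 was 2.55-fold higher, and Tubb3 was 2.65-fold lower, or -0.91 on the log2 scale under normexp. Pancreatic acinar markers had a median of 0.03 (percentile 32.0), or -0.12 after cyclic loess, and 1 of 11 at least 2-fold lower. This was Amy2a5, not above background in the SiO2 pool, whose difference of -1.48 was 0.016 under normexp and whose other probe gave -0.11.

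Hepatocyte genes, measured because the series concerns turning the spleen towards liver, had a median of 0.08 (percentile 43.6) and a mean of -0.08. The median was -0.20 in the authors' deposited values and 0.34 under normexp. Of 19 measured, 2 were at least 2-fold lower, the keratin Krt18 (3.57-fold), which is also in the mesothelial list, and the fetal liver protein Afp (2.3-fold), and none higher. Krt18 (-0.89) and Afp (-0.88) were within 2-fold on the log2 scale under normexp. The liver transcription factor Hnf4a was at -0.05, with dim signals of 16.2 in PBS and 11.0 in SiO2. Of 30 hepatocyte genes listed, only the 19 had a named probe above background, 3 of them on 1 array only. The list thus says little about genes near or under background. Growth factors that support hepatocytes had a median of -0.16 (percentile 5.88), or 0.20 under normexp, with Fgf1 2.24-fold lower and Wnt2 at a bound of 2.0-fold lower that was 0.15 on the log2 scale under normexp. Angiogenesis and endothelial markers had a median of -0.07 (percentile 26.3), or 0.04 under normexp, and 0 of 24 members differing 2-fold. Oxidative stress genes had 5 of 19 members at least 2-fold higher and none lower, with a median of 0.15 (percentile 88.0). These were catalase, Cat (2.61-fold), the glutathione synthesis genes Gclm (2.59-fold) and Gclc (2.26-fold), Nqo1 (2.45-fold) and Gpx1 (2.36-fold). Hypoxia and glycolysis genes had a median of -0.07 (percentile 22.3) and 0 of 22 differing 2-fold.

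Among control genes, Gapdh was at 0.28, Actb at -0.25 and Hprt at 0.14, and under the alternatives listed in advance that gave them a value they ranged from 0.10 to 0.28, from -0.49 to -0.25 and from 0.05 to 0.14. Centred on the difference of B and T cell markers, Gapdh was at 0.69, Actb at 0.16, Hprt at 0.55 and the median of housekeeping genes at 0.46. Cytosolic ribosomal protein genes had a median of 0.18 (percentile 90.3) with 0 of 33 differing 2-fold, and in the authors' deposited values that median was -0.001. Housekeeping genes had a median of 0.05 (percentile 54.1), or -0.02 under quantile normalization, with 2 of 14 at least 2-fold higher, among them Tfrc. Of 9 probes for Y-linked genes, 1 was well above background on each array, that of Sry, at a log2 difference of 0.56 (percentile 74.2) in these female mice. Repeated spots of a probe differed between the arrays with a median standard deviation of 0.063 on the log2 scale, which covers spots and not animals.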

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

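The tests of explanations in this part were chosen after the results were seen. Probes that matched no gene name took no part in the comparison of genes, and they also differed between the pools. Of 8482 such probes above background, 35 were at least 4-fold higher in the SiO2 spleen and 25 at least 4-fold lower. At 2-fold, 419 (4.94%) were higher and 215 (2.53%) lower.

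Erythroid and cell cycle genes were both higher in the SiO2 pool. A trend of the difference with signal was not the whole source of the erythroid part, whose median was 1.56 after cyclic loess, with a lower quartile of 1.21. Carry-over of red cells without a nucleus stays open for the erythroid part. It would not by itself raise cell cycle genes, whose median was 1.07 with a lower quartile of 0.79. These values are part of the pattern itself, so they are no separate test of carry-over. A candidate explanation, untested here, is more blood cell formation in the spleen after SiO2. Of other blood cell lists, neutrophil and granule genes were also higher (median 1.01), while progenitor genes (-0.27) and megakaryocyte and platelet genes (-0.19) were not.

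The lists of interferon-stimulated genes, cytotoxic and NK markers and pan-macrophage markers had lower medians. Dilution by RNA of other cells, where B and T cells share it, would lower them as much as B and T cell markers. Yet relative to those markers the medians were -1.05 for interferon-stimulated genes and -0.74 for cytotoxic and NK markers, with upper quartiles of -0.58 and -0.53. Dilution that those markers do not share was not tested. For pan-macrophage markers the median was -0.28 with an upper quartile of 0.05 when the markers' median difference was set to 0, and -0.48 with an upper quartile of -0.14 when each array was centred on their level, so the centrings differ and dilution stays open there. Fewer NK cells could also lower interferon-stimulated genes. The median of these genes was -0.31 from that of the NK markers, within their spread. Fewer NK cells would set no fixed relation between these medians, so the comparison cannot decide this, and it stays open. An effect of SiO2, or an interferon response in part of the PBS pool, could not be tested on pooled RNA.

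Mesothelial genes showed the lowest median of the lists fixed in advance. Relative to B and T cell markers it was -2.84, with an upper quartile of -0.66, which dilution that lowers those markers as much would not give. The centring cannot address dilution that those markers do not share. Less capsule in the sampled tissue and an effect of SiO2 on the mesothelium both stay open, since no list fixed in advance tests either.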

How the results depend on the processing

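Of the 20 lists that stood apart, 16 did so on the same side under each of the 9 alternatives listed in advance that apply to lists, among them the erythroid (1.45 to 1.62), cell cycle (0.99 to 1.15), interferon-stimulated (-1.54 to -1.32) and mesothelial lists (-4.08 to -0.90). The cause of the shifts below was not tested unless stated. Under normexp, which also took another spot signal, so that signal, correction and offset were not separated, the counts were 655 higher and 259 lower at 2-fold and 51 and 30 at 4-fold, 900 of the 1731 genes at least 2-fold apart stayed so, 73 took the other sign, and the median of all genes was 0.18 in place of 0.03. In the authors' deposited values, which cover 12132 of the genes, 700 were higher and 572 lower at 2-fold (55.0% higher) and 94 and 78 at 4-fold; with no filter and no floor, which admits dim probes, 240 were higher and 144 lower at 4-fold. Lists that ceased to stand apart were red pulp macrophages under normexp (-0.20), chemokines with no filter (-0.17), and immunosuppression (-0.30) and adipocytes (0.22) in the authors' values. Lists that came to stand apart were TGF-beta signalling (-0.27) and oxidative stress (0.28) with the mean over probes, T cell markers without matching (-0.27), and progenitors under quantile normalization (-0.35) and in the authors' values (-0.46). Of 1570 values of named genes, 1533 kept their side of 2-fold and 33 came within it, 24 of these under normexp. Most named genes were chosen from the main values by size or nearness to a list median. Keeping their side is thus partly built in and no measure of stability over all genes. Vsig4 (0.042), Wnt2 (0.15), Cma1 (0.22) and Amy2a5 (0.016) took the other sign under normexp. A pair of centrings on B and T cell markers was chosen after seeing the data, the second of them after the result of the first, which had left the markers' own median difference away from 0. Centring each array on their median level gave 1701 higher and 370 lower at 2-fold and 48 lower at 4-fold, with 82.1% of the 2-fold calls higher against 64.2%, and moved all genes by 0.22. Setting their median difference to 0 gave 2622 and 248 at 2-fold, 346 and 38 at 4-fold and 91.4% higher, and moved all genes by 0.41; the medians of red pulp macrophages (0.12), inflammasome (0.050), chemokines (0.076), immunosuppression (0.060) and dendritic cells (0.034) then lay above 0. Either centring, like scaling to the median, adds 1 value to all genes, so the percentiles of lists cannot move. No spot was saturated, so leaving such spots out moved nothing. Scaling to spike-in probes was not run, since 3 of 10 were above background on either array. No paired analysis was possible because each group has 1 array, which also leaves no replicate to omit. Signal near background limits the dim genes. Where 1 array was not above background the difference is a bound or rests on the probe's own undetected signal, and some genes called above background on both arrays had a processed signal near it on 1 of them, such as Upk3b (8.38 in SiO2) and Vsig8 (9.53 in PBS), whose log2 differences of -5.09 and 4.12 were -2.37 and 1.84 under normexp.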

Other observations

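Lists in this part were chosen after the data were seen, from genes that stood out, and are no independent evidence of direction. Genes of haem biosynthesis were higher in the SiO2 pool, 8 of 9 at least 2-fold, with a median log2 difference of 1.57. Ppox was at 1.95, the erythroid enzyme Alas2 at 1.77 and the form found in most tissues, Alas1, at -0.03. The globin genes were among the brightest on both arrays even though the labels' protocol reduced globin message: Hba-a1 had a processed signal of 45754 in PBS and 47792 in SiO2, and a log2 difference of 0.58.

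Interferon-induced GTPases were lower, 14 of 15 at least 2-fold, with a median of -1.76, Gbp2b at -3.69 and Gbp4 at -2.40. Genes of antigen processing for MHC class I had a median of -0.91, with 5 of 10 at least 2-fold lower, among them Psmb10 at -1.58 and Nlrc5 at -1.56. Ly49 receptors of NK cells had a median of -1.95 and 8 of 10 at least 2-fold lower, although probes of this family of near-identical genes can share signal. Contractile genes of the spleen had a median of -0.77 and 1 of 10 at least 2-fold lower, with Acta2 at -0.91, Tagln at -0.88 and Myl9 at -0.98. These, with Cnn1, Tpm2 and Des, are also in the list of fibroblast and myofibroblast markers, so the lists are not separate observations.

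Other lists did not stand apart. Cholesterol biosynthesis genes had a median of -0.08 with 1 of 15 at least 2-fold higher and 1 lower, the unfolded protein response -0.15 with 0 of 10 differing 2-fold, the heat shock response 0.03 with 1 of 9 lower, Hspb1 at -2.01, and nuclear genes of the respiratory chain 0.18 with 0 of 20 differing 2-fold.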
